A study of Mus musculus with 6 samples.

How the data were processed

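Total RNA of BALB/c mouse retinas was measured on 6 Affymetrix arrays, 3 of dark adapted and 3 of light damaged retinas, grouped by the sample titles. Per the submitters' processing notes the authors made the values with RMA, which corrects the background, normalizes between arrays by quantiles and summarises the probes of each probe set; its version is not given in the sources used here. The deposited values are on the log2 scale, as judged from their range of 3.30 to 13.89. They were used as deposited, without further scaling. RMA brings the arrays to nearly the same distribution (the upper quartiles still ranged from 7.41 to 7.67), so a change in total RNA per retina would not be seen, and it compresses the differences of very dim and very bright probe sets.

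The value table held 45101 probe sets. Of these, 64 were control probe sets, 34945 were assigned to 1 gene by GEO's platform annotation, 932 to several genes and 9160 to none. Symbols were matched through the Entrez identifier to RefSeq genes of the assembly GRCm38.p6, used here only for names, which held 34741 of the probe sets with 1 gene and changed 0 symbols. No coordinates are given, as the sources used here name no genome build. For each gene the probe set with the highest mean over the 6 arrays was taken among those assigned to that gene alone, which gave 18193 genes. Of the 365 genes called, 206 had several probe sets, and in 45 of these a further probe set had the opposite sign. Probe sets were not filtered by level.

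Groups were compared with limma 3.58.1 (lmFit and eBayes, without a trend) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Changes are log2 values of light damaged minus dark adapted retinas, and folds are 2 to the power of their size. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 31 lists; 25 of these were of main interest (rod photoreceptor, cone photoreceptor, bipolar cell, amacrine and horizontal cell, retinal ganglion cell, Müller glia identity, reactive glia, endothelin and trophic factor signalling, JAK-STAT signalling, immediate early and AP-1, complement, microglia and macrophage, chemokine and cytokine, interferon response and antigen presentation, oxidative stress and metallothionein, iron handling, heat shock and unfolded protein response, crystallin, cell death and p53, cell cycle, extracellular matrix and protease, circadian clock, visual cycle, sterol synthesis and glycolysis) and 6 served as checks (retinal pigment epithelium, lens, vascular, blood cell, reference and sex-linked genes). The lists held 529 genes, of which 479 were analysed here, each by a probe set assigned to that gene alone. Camera called 16 lists, 13 higher and 3 lower, and 17 with the replicate block alone. With the correlation estimated from the data, 8 of the lists passed the threshold. With the replicate block added to this estimated correlation none did. Where a list value is given below with the replicate block added, both settings were used together. Values of single measures were compared with exact two-sided permutation tests.

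The genes named were set by rule: the 10 largest rises and 8 largest falls past the threshold without overlap between groups, skipping predicted or clone-based names (1 skipped), up to 2 members with the largest change past the threshold per main list, or else the 1 member with the smallest p, the 1 member with the smallest p per check list, and Gfap, Edn2 and Fgf2, with 1 further gene that is not reported here. The rule gave 56 genes with values. The groups, tests, lists, rule and alternatives were fixed before the data were examined, except where stated.

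The titles number the replicates 1 to 3 in both groups. Whether the numbers pair the arrays was checked from the correlation, over probe sets, of their deviations from the group means. It was 0.732, 0.618 and 0.432 for arrays of the same number and between -0.48 and 0.00917 for others. All 3 exceeded 0.1, so the numbers were taken to pair the samples, from the data and not from a label that says so. This limit is not a test of the pairing. Deviations sum to 0 within each group, so the values for other arrays are partly fixed by these 3 and are not separate evidence. All results with the block rest on this pairing, which was inferred from the same values. Values with the replicate number as a block are given where they change a call or move a count by over 1.5 times. The median standard error was 0.162 without and 0.112 with the block.

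The fit was tested on simulated data with the 18193 genes' means, with 200 genes changed. With gene variances drawn from limma's prior it recovered 0, 64, 96 and 100% of changes of 0.5, 1, 2 and 3 on the log2 scale, with 7 false calls, and with the replicate block 24, 100, 100 and 100%, with 6 false calls. With limma's posterior variances it recovered 6, 84, 100 and 100% with 16 false calls, and with the block 62, 100, 100 and 100% with 17. The bipolar cell list, the only one shifted (by 0.5), was called and no other of the 31 lists was. The noise was drawn independently for each gene. This therefore cannot show how often correlated genes would give false list calls. Alternatives covered the replicate block, filters on dim genes, the choice among a gene's probe sets, 3 scalings between arrays, a variance trend with robust fitting, array weights, a fold threshold, all probe sets, other list tests and leaving out each array. Probe sets with several genes or none were left out of the gene counts and counted apart. Figures were drawn with matplotlib 3.10.9.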

Results

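RNA was measured in the retinas of BALB/c mice, an inbred albino strain whose unpigmented eyes are sensitive to strong light. All mice were kept in the dark for 1 week. Part of them then received 6000 lux of white fluorescent light for 6 h, which injures photoreceptors (light damage), and their retinas were taken 24 h later. The series holds 6 Affymetrix arrays, on which each gene is read by short oligonucleotide probe sets, with 3 arrays of light damaged and 3 of dark adapted retinas. The comparison addresses how RNA levels in the retina differ after light damage. The values are log2 expression values made with RMA (robust multi-array average), and their medians lay between 6.15 and 6.18 on the 6 arrays. The number of arrays limits the precision of every value below. The labels do not say that the replicates are separate animals, so the p-values measure only the spread between these samples, which may be technical.

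Light damaged retinas carried much more RNA of Cebpd, a transcription factor of acute-phase responses, of Lcn2, an iron-siderophore binding protein, and of Edn2, which encodes the secreted peptide endothelin 2. Cebpd rose from 6.30 ± 0.62 to 10.57 ± 0.22 (log2, mean ± SD, n = 3 per group), a 19.3-fold rise, Lcn2 rose 17.9-fold and Edn2 12.9-fold. The next largest rises were those of Lgals3 (galectin 3, 8.83-fold), the oncostatin M receptor gene Osmr (8.24-fold), the metallothionein gene Mt2 (7.52-fold), Crym (mu-crystallin, a thyroid hormone binding protein, 7.06-fold), Pdpn (podoplanin, 6.87-fold), the endothelin receptor gene Ednrb (6.72-fold) and the hyaluronan receptor gene Cd44 (6.07-fold). The falls were smaller. Glb1l3 and Glb1l2, both related to beta-galactosidase, fell by 2.07 and fell by 1.66 on the log2 scale, and Opn1sw, the short-wavelength cone opsin, fell by 1.62. Samd11 fell by 1.61, the lipid phosphatase gene Plpp2 fell by 1.58, Hcls1 fell by 1.52, the transcription factor gene Mef2c fell by 1.51 and Rabgef1, a regulator of endosomal traffic, fell by 1.47.

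Of 18193 genes tested with limma, 365 changed at an adjusted p under 0.05, 316 of them higher and 49 lower in light damaged retinas, and 2002 had an unadjusted p under 0.05. At least 2-fold changes made up 191 of the rises and 31 of the falls, and 220 and 54 with the replicate block. In all 365 genes the 3 light damaged values lay outside the range of the 3 dark adapted ones. Over all genes this held for 15.6%, against 10% by chance if all arrays were independent, which the pairing puts in doubt. The standard errors of the 18 genes named above were between 0.16 and 0.40 and their adjusted p between 0.000757 and 0.0308. Other probe sets of Osmr, Cd44 and Samd11 gave changes of the opposite sign (-0.12, -0.20 and 0.16). Much smaller changes of the same sign came from other probe sets of Cebpd (0.58), Ednrb (1.15) and Plpp2 (-0.08). The folds above hold for the chosen probe set only. With the replicate number as a block, 1613 genes changed, 1225 higher and 388 lower, the 365 among them. Quantile normalization of the values again gave 325 higher and 162 lower. Centring each array on the reference genes gave 127 higher and 589 lower, with the median change of all genes at -0.39 in place of 0.03. Of these 8 reference genes 1 rose past the threshold, but 7 had positive changes and the mean change over the 8 was 0.42. Centring subtracts this mean rise from every gene, which by construction moves calls from higher to lower. Without dark adapted replicate 2 the count was 180, without light damaged replicates 1, 2 and 3 it was 212, 151 and 159, and without dark adapted replicate 3 the lower genes numbered 82. With 1 array left out, Hcls1, Rabgef1 and Glb1l2 each lost the call at least once (adjusted p up to 0.109, 0.165 and 0.0763).

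**Figure D1:**
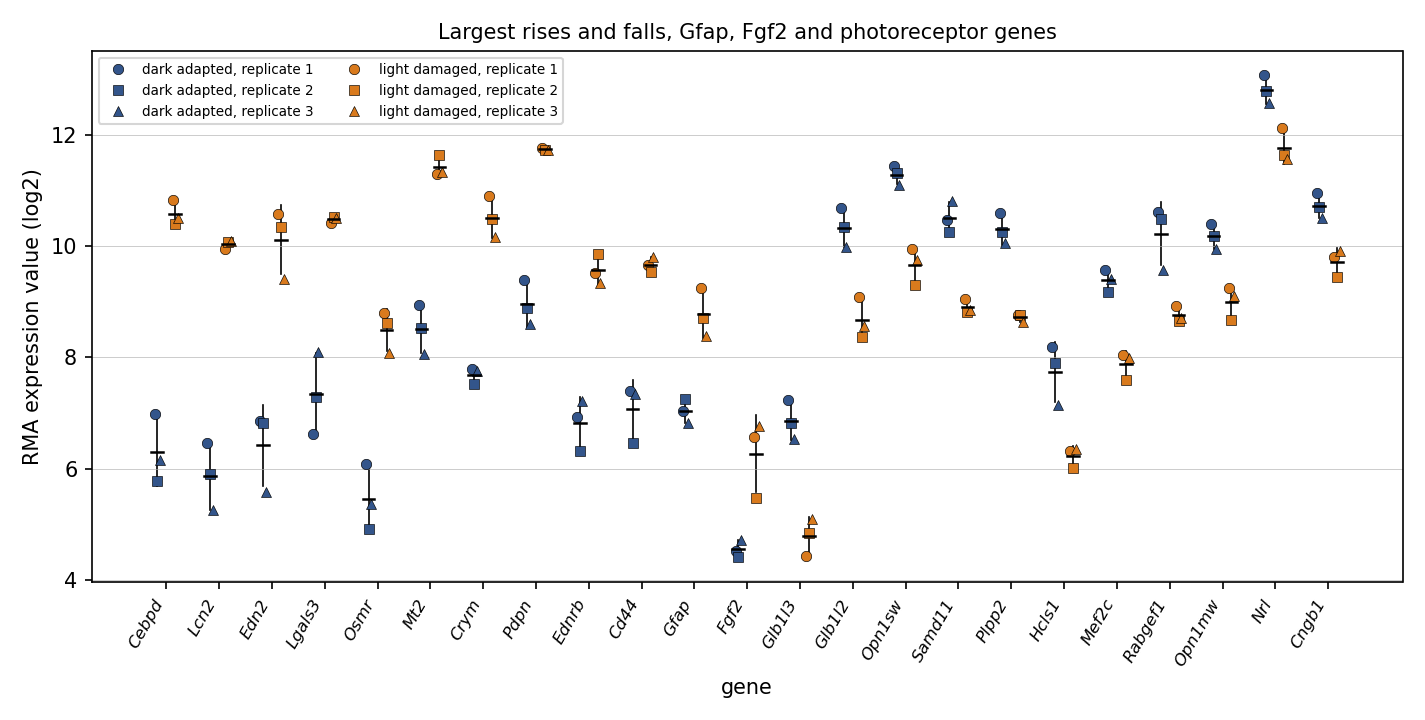
RMA values (log2, vertical axis) of the 10 largest rises, Gfap, Fgf2, the 8 largest falls, and the photoreceptor genes Opn1mw, Nrl and Cngb1 (horizontal axis) on each of 6 arrays, with dark adapted arrays in blue and light damaged ones in orange, and circles, squares and triangles for replicates 1, 2 and 3. Bars are means and vertical lines ± SD over 3 arrays; the groups do not overlap in any of these genes, with means of 6.30 and 10.57 for Cebpd and of 11.28 and 9.66 for Opn1sw.

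Some photoreceptor genes fell after light damage. Of 28 measured rod genes, Nrl, the transcription factor that directs rod fate, and Cngb1, a subunit of the rod cyclic-nucleotide gated channel, fell by 1.04 and 1.00, and 26 did not pass the test, although 27 of the 28 changes were negative and their median was -0.59. Rod genes that fell numbered 18 adjusted over the list alone, and with the replicate block 18 fell over all genes. Of 12 measured cone genes 3 fell, with Opn1sw and the medium-wavelength opsin gene Opn1mw leading (-1.62 and -1.18), 9 did not pass, and the median was -0.30. Adjusted over the list alone 3 cone genes fell and 1 rose, and with the replicate block 4 fell and 1 rose. The gene that rose in both was Gnb3, named after its values were seen, which encodes a G protein subunit of cones and ON bipolar cells (1.03, adjusted p = 0.123 over all genes and 0.000827 with the block). The rod list was lower in the camera test (adjusted p = 6.32e-21), and its call was lost with an estimated correlation (adjusted p = 0.195 with an estimated correlation). The cone list was lower as well (adjusted p = 6.97e-06; adjusted p = 0.0787 with an estimated correlation). Nrl, Cngb1 and Opn1mw each lost the call with 1 array left out (adjusted p up to 0.192, 0.116 and 0.0887).

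The rod and cone lists were compared directly. The mean log2 level of the rod list lay above that of the cone list by 2.73 ± 0.13 (SD, n = 3) in dark adapted and by 2.58 ± 0.12 (SD, n = 3) in light damaged retinas. The groups differed by -0.15, with a two-sided p of 0.3 in an exact permutation test, where 3 arrays against 3 cannot give a p below 0.1. Within the 3 same-numbered pairs the differences were -0.16, -0.15 and -0.14, all of 1 sign (exact sign-flip permutation test, two-sided p = 0.25, the smallest that 3 pairs can give). The mean change was -0.59 in the rod list and -0.44 in the cone list. The cone mean includes Gnb3, which rose by 1.03 and is also a gene of ON bipolar cells. As the difference was not computed without Gnb3, it does not show that rod genes fell more than cone genes.

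Genes of reactive glia, the astrocytes and Müller cells of injured nervous tissue, were higher as a list. Of 22 measured members 13 rose, none fell and 9 did not pass, with a median change of 1.55; adjusted over the list alone 14 rose. Lcn2 and Osmr led them, with log2 changes of 4.16 ± 0.27 and 3.04 ± 0.30 (SE). Gfap, the intermediate filament of activated glia, rose from 7.03 ± 0.21 to 8.78 ± 0.44 (mean ± SD, n = 3 per group), a 3.36-fold rise with adjusted p = 0.00693. The list was higher in the camera test (adjusted p = 1.79e-19; adjusted p = 0.0197 with an estimated correlation and 0.19 with the replicate block added). The list of genes that mark Müller cells at rest was not called. Crym and Sox2, a transcription factor of neural progenitors and Müller cells, rose (2.82 and 1.12), 13 of 15 did not pass, and the median change was -0.02 while the mean was 0.24 (camera, higher, adjusted p = 0.416). Adjusted over the list alone 6 of them rose and 1 fell, and with the replicate block 6 rose and 3 fell. The 3 were Glul (-0.99, limma adjusted p = 0.000775 with the block), Abca8a (-0.55, 0.0249) and Rlbp1 (-0.50, 0.0329), named after their values were seen. The median near 0 therefore covers changes in both directions. Sox2 lost the call with 1 array left out (adjusted p up to 0.127) and in the fit on reference-centred arrays (adjusted p = 0.0649).

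Some endothelin and trophic factor genes and some genes of JAK-STAT signalling, through which cytokines of the interleukin 6 family act, rose. In the endothelin and trophic factor list 6 of 19 genes rose, none fell and 13 did not pass, and adjusted over the list alone 8 rose, the same number as with the replicate block. Edn2 went from 6.42 ± 0.73 to 10.11 ± 0.62 and Ednrb from 6.82 ± 0.46 to 9.57 ± 0.26 (mean ± SD, n = 3 per group). Fgf2, a growth factor that supports photoreceptors, rose 3.29-fold (log2 change 1.72 ± 0.31, SE, adjusted p = 0.031), and lost the call with 1 array left out (adjusted p up to 0.142). Its dark adapted values (4.41 to 4.72) lay below the lower quartile of every array (4.98 to 5.11), so this fold is uncertain. Of 17 JAK-STAT genes 8 rose, none fell and 9 did not pass, with Cebpd and Bcl3, a partner of NF-kappaB (2.41), the largest; adjusted over the list alone 9 rose. The camera test gave adjusted p = 6.94e-05 for the endothelin and trophic factor list and 2.91e-13 for the JAK-STAT list. Both kept the call with an estimated correlation (adjusted p = 0.0402 for each) and with the replicate block alone (0.000276 and 2.21e-10). With both settings together they lost it (adjusted p = 0.219 for each).

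Many interferon response and antigen presentation genes rose. Of 22 members 15 rose, none fell and 7 did not pass, with a median change of 1.16, and adjusted over the list alone 19 rose. Oasl2, an interferon-induced gene, rose 4.56-fold and Tap1, a peptide transporter of antigen presentation, 4.33-fold, although another probe set of Tap1 gave -0.22 and the mean of its probe sets did not pass (adjusted p = 0.0658). The camera test gave adjusted p = 1.29e-27, and adjusted p = 0.0197 with an estimated correlation and 0.19 with the replicate block added. In the complement list 3 of 13 genes rose, none fell and 10 did not pass; adjusted over the list alone and with the replicate block 7 rose. Serping1, the inhibitor of the C1 protease, rose 3.94-fold and C1qc 2.41-fold, the latter with adjusted p up to 0.113 when 1 array was left out (list adjusted p = 4.41e-07; adjusted p = 0.0318 with an estimated correlation and 0.244 with the replicate block added).

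Some markers of microglia and macrophages and some chemokine genes rose. Of 22 microglia and macrophage genes 4 rose, none fell and 18 did not pass, among them Lgals3 (3.14) and Cd68, a lysosomal protein of phagocytes (1.88 ± 0.22, SE). The median change of the list was 0.26. Adjusted over the list alone 7 rose and 1 fell, as with the replicate block. The gene that fell with the block was P2ry12 (-0.48, limma adjusted p = 0.0199), named after its values were seen. The list was higher (camera adjusted p = 9.91e-05), and lost the call with an estimated correlation (adjusted p = 0.191 with an estimated correlation). Of 22 chemokine and cytokine genes 3 rose, none fell and 19 did not pass; adjusted over the list alone 9 rose and with the replicate block 10. Cxcl12 and Ccl12 rose 2.23-fold and 2.15-fold. The dark adapted values of Ccl12 (4.62 to 4.73) lay below the lower quartile of every array (4.98 to 5.11), so its fold is uncertain. Another probe set of Cxcl12 gave -0.60, the mean of its probe sets did not pass (adjusted p = 0.62), and its call was lost with 1 array left out (adjusted p up to 0.121). The chemokine list was higher (adjusted p = 6.94e-05; adjusted p = 0.167 with an estimated correlation).

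A minority of stress genes rose. The immediate early and AP-1 list holds genes induced within minutes to hours of a stimulus, many of them for transcription factors. Of its 22 genes 5 rose, none fell and 17 did not pass. Adjusted over the list alone 7 rose and with the replicate block 11. Junb rose 4.54-fold and Atf3 3.32-fold (list adjusted p = 1.67e-09; adjusted p = 0.0315 with an estimated correlation and 0.219 with the replicate block added). Of 18 oxidative stress and metallothionein genes 4 rose, none fell and 14 did not pass; adjusted over the list alone 10 rose and with the replicate block 12. Its leading members were the zinc-binding metallothioneins Mt2 and Mt1 (2.91 and 2.32), where Mt1 did not pass once probe sets that match several transcripts were left out (adjusted p = 0.845). The list was higher (adjusted p = 6.98e-10; adjusted p = 0.0318 with an estimated correlation and 0.219 with the replicate block added). The heat shock and unfolded protein response list had 1 rise among 19 genes, that of the transcription factor gene Atf5 (0.93, adjusted p up to 0.158 with 1 array left out), no fall and 18 that did not pass. Adjusted over the list alone 6 rose, and with the replicate block 7 rose and 1 fell (list adjusted p = 0.000352; adjusted p = 0.195 with an estimated correlation).

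Of 20 cell death and p53 genes 3 rose, none fell and 17 did not pass, and 6 rose adjusted over the list alone and with the replicate block. Gadd45b, a stress-induced gene, rose 3.66-fold and Tnfrsf1a, the main receptor of tumour necrosis factor, 2.30-fold; Gadd45b lost the call with 1 array left out (adjusted p up to 0.0776). The list was higher with adjusted p = 0.0119, and this call was lost with an estimated correlation (adjusted p = 0.195 with an estimated correlation), without dark adapted replicate 1 (adjusted p = 0.115) and without light damaged replicate 3 (adjusted p = 0.0663). Of 21 extracellular matrix and protease genes 3 rose, none fell and 18 did not pass, with 9 risen adjusted over the list alone and 10 with the replicate block. The metalloprotease gene Adamts1 and the protease inhibitor gene Timp1 rose 2.78-fold and 2.68-fold, the latter with adjusted p up to 0.123 when 1 array was left out (list adjusted p = 6.97e-06; adjusted p = 0.0402 with an estimated correlation and 0.219 with the replicate block added). In the cell cycle list Ccnd1 (cyclin D1) rose 2.81-fold, 19 of 20 genes did not pass, and the list was not called (adjusted p = 0.127). In that list 1 gene rose adjusted over the list alone and 3 with the replicate block. In the iron handling list Lcn2 and the ferroxidase gene Cp (2.13 ± 0.19, SE) rose, 1 gene fell and 9 of 12 did not pass, with the same counts adjusted over the list alone; the list was not called (adjusted p = 0.533). Other probe sets of Cp lay between -0.05 and 3.03. Lcn2 and Cp are also members of the reactive glia list, as is Timp1.

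**Figure D2:**
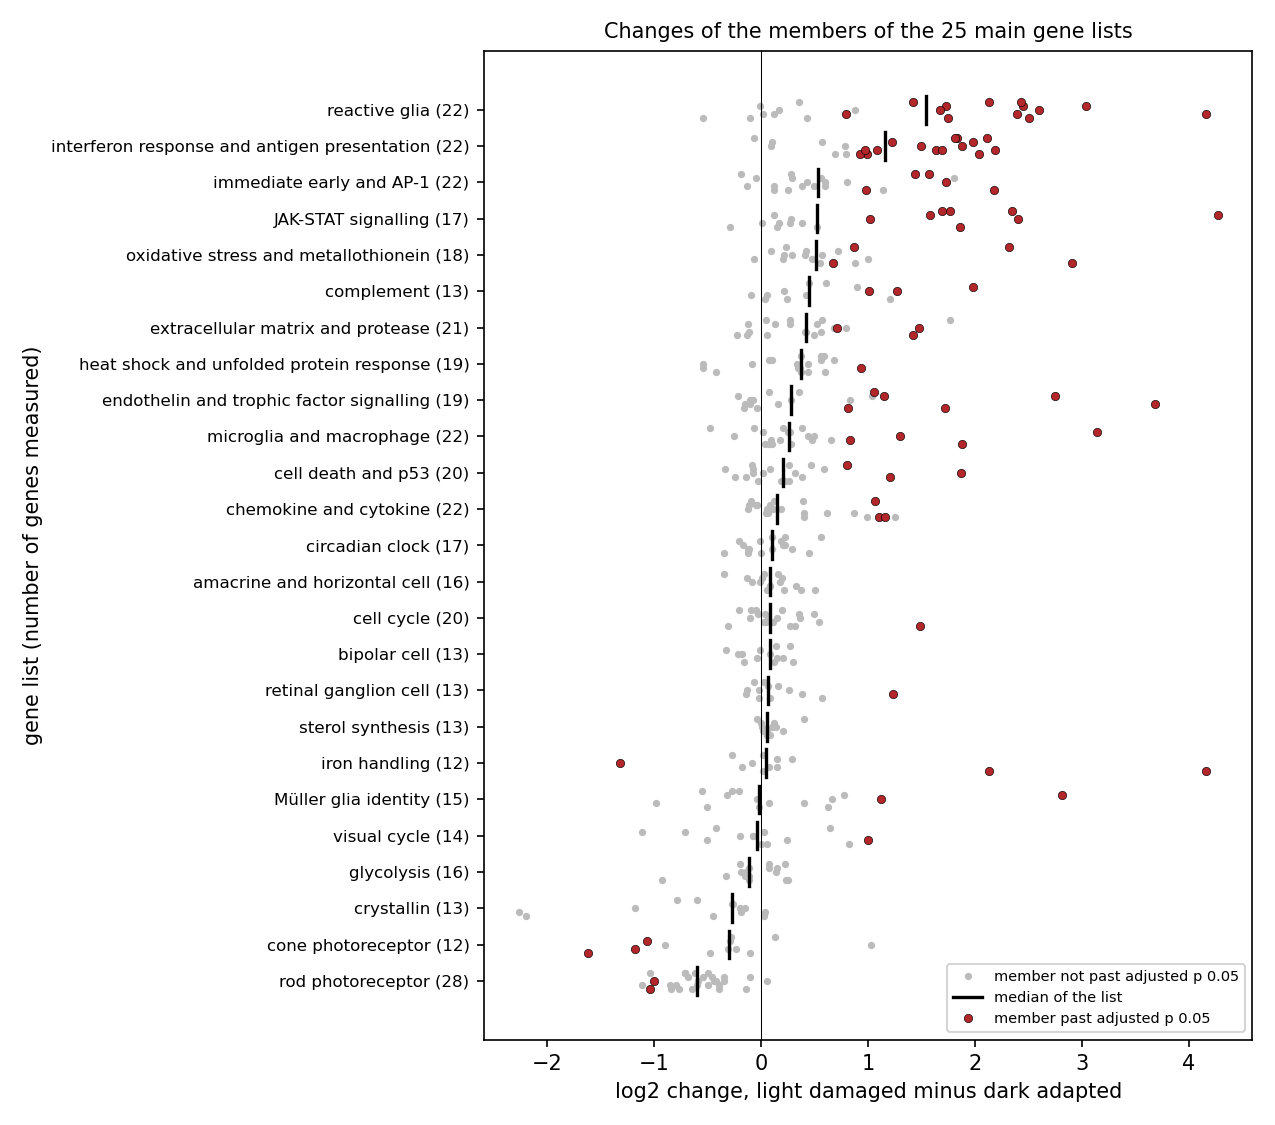
Log2 change, light damaged minus dark adapted (horizontal axis), of every measured member of the 25 main gene lists (vertical axis, number of measured genes in brackets), 3 arrays per group. Red points passed an adjusted p of 0.05, grey points did not and black bars are list medians, which run from -0.59 for rod genes to 1.55 for reactive glia.

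Other neurons and metabolic lists showed few changes. Of 13 bipolar cell genes none passed, and the list's median and mean changes were 0.08 and 0.03 while camera placed it lower than other genes (adjusted p = 0.817); Trpm1, a channel of ON bipolar cells, had the smallest p of its members (0.30, adjusted p = 0.667). Of 16 amacrine and horizontal cell genes none passed, with Pax6, a transcription factor of retinal development, at 0.37 (adjusted p = 0.233) and the list at adjusted p = 0.43; with the replicate block 1 rose. Of 13 retinal ganglion cell genes Gap43, a growth cone protein, rose 2.35-fold, 12 did not pass, and the list was not called (adjusted p = 0.277). In the visual cycle list Rdh10, a retinol dehydrogenase, rose 2.00-fold, with adjusted p up to 0.0839 when 1 array was left out, and 13 of 14 did not pass. Adjusted over the list alone 2 rose and 2 fell, and with the replicate block 1 rose and 3 fell (list adjusted p = 0.43). None of 17 circadian clock genes (Bhlhe40 at 0.56, adjusted p = 0.0978, and 0.00972 with the replicate block), of 13 sterol synthesis genes (Msmo1 at 0.40, adjusted p = 0.424, and 0.0454 with the block) or of 16 glycolysis genes (the lactate transporter gene Slc16a1 at -0.93, adjusted p = 0.226, and 0.000816 with the block) passed. No member passed adjusted over the list alone in the bipolar, amacrine and horizontal, circadian, sterol and glycolysis lists and 1 ganglion cell gene rose. The list tests gave adjusted p = 0.892, 0.518 and 0.195 for the circadian, sterol and glycolysis lists. On reference-centred arrays the changes of Trpm1, Pax6 and Msmo1 were -0.12, -0.05 and -0.03.

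Crystallins, the structural proteins of the lens, some of which are also made in the retina, were measured because a dissection can carry lens along. None of 13 passed over all genes or adjusted over the list alone, and 4 fell with the replicate block. Crygf, the member with the smallest p, went from 9.42 ± 0.98 to 8.24 ± 0.49 (mean ± SD, n = 3 per group; adjusted p = 0.357, and 0.00232 with the block). It shares sequence with near-identical gamma crystallin genes, so its values are uncertain. The list was lower in the camera test (adjusted p = 0.00434), and this call was lost with an estimated correlation (adjusted p = 0.625 with an estimated correlation), without dark adapted replicate 3 (adjusted p = 0.74) and without light damaged replicates 1 and 2 (adjusted p = 0.143 and 0.086), and its direction turned on reference-centred arrays (adjusted p = 0.915). The lens list, which holds Cryaa and Crygs as well, had no member past the test among 8 and a median change of -0.31. It was not called without the block (adjusted p = 0.127; adjusted p = 0.745 with an estimated correlation) and was lower with it (adjusted p = 0.000533), where 2 members fell; that call was lost with an estimated correlation (adjusted p = 0.219 with an estimated correlation). The lens filament gene Bfsp1 was at 8.33 ± 1.34 and 7.21 ± 1.34 (mean ± SD, n = 3 per group; adjusted p = 0.735, and 0.00028 with the block). Of 18 crystallin and lens genes, which left out Hspb1 of the lens list, 16 were higher in both replicate 3 arrays than in the other 4.

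**Figure D3:**
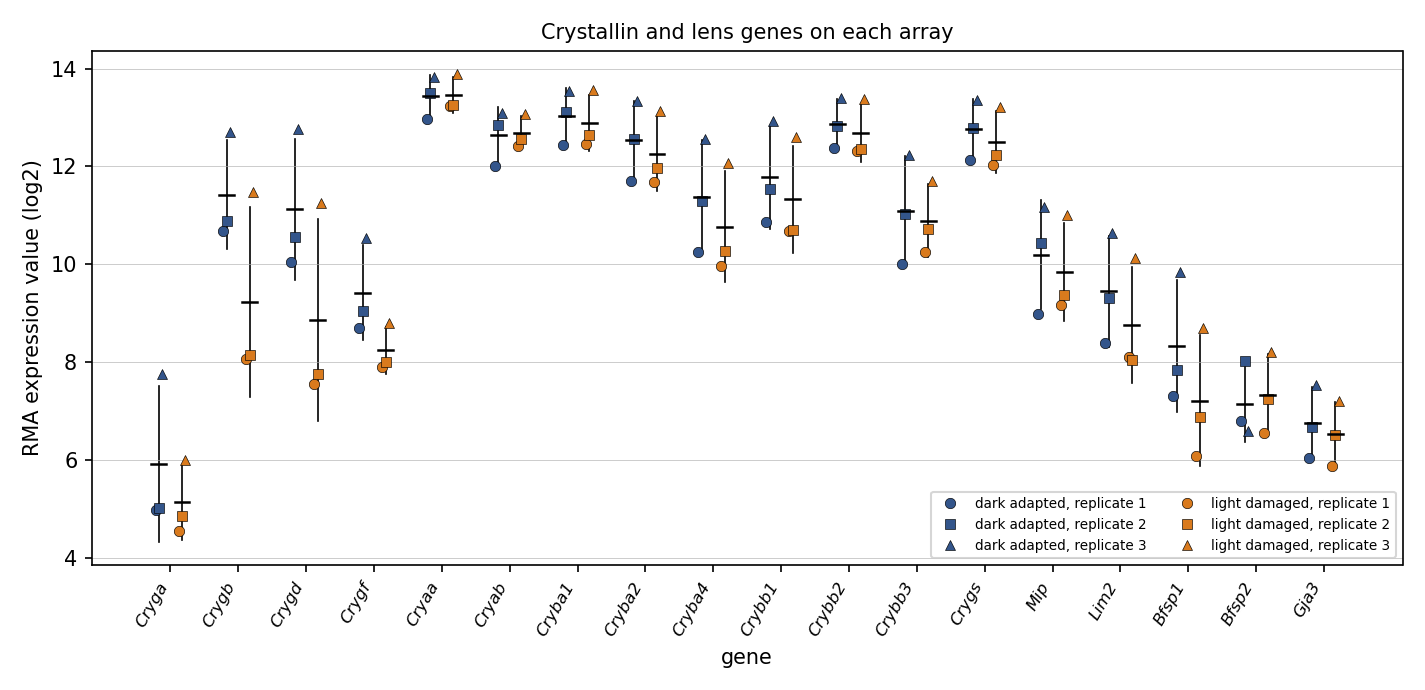
RMA values (log2, vertical axis) of 4 gamma crystallin genes and 14 other lens genes, Crygs among them (horizontal axis) on each of 6 arrays, with dark adapted arrays in blue, light damaged ones in orange and circles, squares and triangles for replicates 1, 2 and 3. Bars are means and vertical lines ± SD over 3 arrays. Crygd was at 10.05 and 7.56 in dark adapted and light damaged replicate 1, while Cryaa was at 12.97 and 13.24. Neither stands for its whole set. In the same pair the gamma crystallin gene Cryga was at 4.98 and 4.55, below the lower quartile of both arrays. The other lens gene Bfsp1 was at 7.30 and 6.07. Hspb1 of the lens list is not shown.

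Lists of other tissues and of technical interest were tested in the same way. Pigment epithelium genes were not called as a group (14 measured, none passed over all genes or adjusted over the list alone, median -0.03, mean 0.03, adjusted p = 0.565), and Rrh, an opsin of that tissue, had a change of -0.71 (adjusted p = 0.174, and 0.0028 with the replicate block, where 1 gene rose and 1 fell). None of 12 vascular genes, 10 blood cell genes or 4 sex-linked genes passed, over all genes or adjusted over the list alone, with list adjusted p of 0.426, 0.252 and 0.279. Their members of smallest p were Kdr, an endothelial receptor (0.44, adjusted p = 0.191, and 0.0318 with the block), the T cell gene Cd3g (-0.25, adjusted p = 0.636) and the Y-linked gene Kdm5d (-0.20, adjusted p = 0.725). Among 8 reference genes, often taken as constant, the ribosomal protein gene Rplp0 rose 2.30-fold and 7 did not pass, with a median change of 0.29. Of the reference genes 3 rose adjusted over the list alone, and 3 with the replicate block. The reference list was higher (adjusted p = 0.00162; adjusted p = 0.285 with an estimated correlation and 0.367 with the replicate block added).

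Measures of RNA quality were set side by side. The 3′ minus 5′ difference of the actin control probe sets was 0.85 in dark adapted and 0.78 in light damaged retinas, and that of the Gapdh control probe sets -0.10 and -0.14; exact permutation tests gave two-sided p of 0.7 and 0.4, where the smallest possible is 0.1. Among 7 such measures, which took in 18S ribosomal RNA, the array median and 3 spiked-in control RNAs, the lowest exact permutation p was 0.3, in a design where none could pass 0.05. The 3 spiked-in control RNAs were higher in the light damaged array of each same-numbered pair, bioC by 0.17, 0.29 and 0.53, bioD by 0.20, 0.14 and 0.57 and cre by 0.23, 0.21 and 0.24 (exact sign-flip permutation p = 0.25 for each, the smallest that 3 pairs can give). Dark adapted replicate 3 stood apart. Its mean correlation with the other arrays was 0.966, against 0.975 to 0.979 for the others, and 861 of its probe sets lay more than 1 log2 unit from their group's median, against 61 to 187. Without both replicate 3 arrays, an alternative chosen after seeing the data, 65 genes changed with no block and 3166 with the replicate block.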

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

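The tests of the lens, pigment epithelium and rod patterns below were chosen only after the results were seen; the splits of the arrays were planned.

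Probe sets that entered no gene-level comparison also differed between the groups in the same limma test. Among 9160 probe sets assigned to no gene, 25 were higher and 6 lower in light damaged retinas, and among 932 probe sets assigned to several genes 20 were higher and 1 was lower.

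The count of 365 changed genes was set against all 10 splits of the 6 arrays into 3 and 3. Only the real split, 1 of the 10, gave as many, and the highest count of the others was 0, as it was for the other splits that part all 3 pairs. With the replicate block, 1 of the 4 splits that part all 3 same-numbered pairs gave as many as the real 1613, and the highest of the others was 0. The other 6 of the 10 splits part 1 pair only. At an unadjusted p under 0.05 limma gave 2002 genes in the real split, 18 to 78 in the others that part all 3 pairs, and up to 2989 in those that part 1 pair, which keep paired arrays together; with the block it gave 4122 against 41 to 291. The splits are too few for a share under 0.05 in either case.

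The gamma crystallin genes Cryga, Crygb, Crygd and Crygf were lower in light damaged retinas than in their same-numbered controls, with median changes of -1.64, -1.89 and -1.62 in pairs 1, 2 and 3 over these 4 genes; Crygs, a further gamma crystallin counted here among the other lens genes, was at -0.10, -0.55 and -0.14. Less lens tissue carried along would lower other lens genes alike, since dark adapted replicate 3, compared with dark adapted replicate 1, had both sets higher (medians of 2.36 for gamma crystallin genes, 2.22 for 8 other lens genes of a mean level under 12 and 1.55 for all 14 others). Within the pairs the medians of these 8 were -0.22, -0.90 and -0.42, and the smallest gap to the 4 gamma crystallin genes was 0.998. The gap exceeded the standard deviation of the 8 genes in each pair (0.45, 0.38 and 0.81). It did not exceed that of the 4 gamma crystallin genes in every pair (1.14, 1.30 and 0.25), so less lens tissue as the whole cause could not be excluded. Cryga lay below the lower quartile of each array in replicates 1 and 2 (4.98 and 5.02 dark adapted, 4.55 and 4.85 light damaged). This left it little room to fall. Its small changes there (-0.43 and -0.17) widened the spread of the 4 genes, and the gap was not computed without it. Also open and untested are a different part of the lens carried along, probe sets shared between near-identical gamma crystallin genes, and an effect of the light, which may be no more than a hypothesis as the gene set was picked from the data.

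Ttr, Rgr and Rdh5, genes active in pigment epithelium, were higher in light damaged replicates 1 and 2 (Ttr at 9.26 and 10.08) than in the 3 dark adapted arrays (8.08 to 8.55), which did not hold for Rgr in replicate 3 (5.97 against 6.42 to 6.68 in the dark adapted arrays). Pigment epithelium carried along with these 2 retinas could account for this. Of 12 other genes on the list, 1 (Krt8) lay above all 3 dark adapted arrays in both, and the tissue's marker Rpe65 was at 6.44 and 6.52 against 6.38 to 6.91. As only 3 of the 12 had a dark adapted mean above the upper quartile of all probe sets, a small share of this tissue cannot be told apart from a change in the retina, and an effect of the light on these genes stays open and untested.

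Rod genes were lower by unequal amounts, from -1.11 for Rdh12 to 0.05 for Rbp3, both named after their values were seen. Loss of a common share of rod RNA read alike by all probe sets was tested by drawing 10000 sets of 28 changes around 1 common change (-0.57) with the within-pair standard errors. The standard deviation of the changes was 0.29 against a median standard error of 0.12. The share of draws with as large a variance was at most 1e-04, the floor to which lower shares were raised. Signal compression of the brightest probe sets as the whole cause was tested on the 13 rod genes with a dark adapted mean under 12, where the share was again at most 1e-04 and the standard deviation 0.26. Both argue against these explanations as the whole cause only if the RNA of each gene comes from rods alone. Whether other cells also carry RNA of these genes was not tested, so loss of rods stays open. Probe sets that respond unequally for other reasons, and gene by gene regulation in rods after light, remain open too. These may act together.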

How the results depend on the processing

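The alternatives that leave out both replicate 3 arrays or join the block with an estimated correlation were chosen after seeing the data; all others were planned, and the cause of a change was not tested except where the construction gives it. With the replicate block 1613 genes changed (1225 higher, 388 lower), and the lens list passed (0.000533), which it did not with an estimated correlation added (0.219); the block changed no other list's call and none of the 45 calls among named genes. Array weights gave 1362 (1097 and 265), quantile normalization again 162 lower genes, reference-centred arrays 716 (127 and 589), the 2-fold threshold, stricter by construction, 222 (191 and 31), the block without both replicate 3 arrays 3166 (1966 and 1200), and no block without them, with fewer arrays, 65 (55 and 10). Centring on the reference genes lowers every change by their mean rise of 0.42, by construction. With 1 array left out the counts lay between 151 and 417 (141 to 384 higher, 9 to 82 lower).

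Of the list calls, cell death was lost among genes above the median level (adjusted p = 0.326). With an estimated correlation the rod (0.195), cone (0.0787), microglia (0.191), chemokine (0.167), heat shock (0.195), crystallin (0.625) and cell death (0.195) lists were lost. Fry tests a list's changes against 0, where camera compares them with other genes, so its values answer another question: the rod (0.0737), crystallin (0.733) and reference (0.0514) lists did not pass it, and it placed the bipolar (0.785) and pigment epithelium (0.978) lists higher, as their positive means do, where camera placed them lower. Fry with the block was a setting outside the alternatives counted here. Of the lists that camera called, it did not pass the cone (0.0823), heat shock (0.055), crystallin (0.116) and reference (0.0823) lists. The others passed, from 0.004 for reactive glia and interferon to 0.0478 for rod, as did cell cycle (0.022) and blood cell (0.0292). In camera the reference list was also lost with an estimated correlation (0.285), and with the block added to it (0.367), but not with the block alone (0.00354). With the block and an estimated correlation, which leaves few degrees of freedom, no list passed: rod 0.259, cone 0.367, reactive glia 0.19, endothelin and trophic factor 0.219, JAK-STAT 0.219, immediate early 0.219, complement 0.244, microglia 0.219, chemokine 0.288, interferon 0.19, oxidative stress 0.219, heat shock 0.367, crystallin 0.327, cell death 0.288 and extracellular matrix 0.219. Main lists gained were cell cycle, higher above the median (0.0243) and 25th percentile (0.04) level, without probe sets of several transcripts (0.0407), after quantile normalization (0.0233) and on reference-centred arrays (0.0497); glycolysis, lower after quantile normalization (0.000959), on reference-centred arrays (0.0497), with the block without both replicate 3 arrays (0.0276), without dark adapted replicate 3 (0.00483) and without light damaged replicate 1 (0.00773); and Müller glia identity (0.0497) and iron handling (0.0443), higher on reference-centred arrays. Of the check lists, lens was lower with the block without both replicate 3 arrays (2.8e-05), without dark adapted replicate 1 (0.00297) and without light damaged replicate 3 (0.000186), and blood cell without dark adapted replicate 1 (0.0329).

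Directions turned in the crystallin list, which had passed, and in lists that had not. The circadian list turned lower above the median (0.868) and 25th percentile (0.941) level, with mean probe sets (0.969), without probe sets of several transcripts (0.991), after quantile normalization (0.572), on reference-centred arrays (0.91) and with the block without both replicate 3 arrays (0.523). After quantile normalization the amacrine and horizontal (0.993), Müller glia identity (0.899) and sterol (0.833) lists turned lower. On reference-centred arrays the sterol list turned lower (0.819) and the crystallin (0.915), pigment epithelium (0.444) and lens (0.521) lists higher, and Trpm1 (-0.12), Pax6 (-0.052) and Msmo1 (-0.025) turned. The pigment epithelium list turned higher with array weights (0.524) and with the block without both replicate 3 arrays (0.223). With 1 array left out, the bipolar list turned higher without dark adapted replicate 1 (0.838) and light damaged replicate 2 (0.881), glycolysis higher without dark adapted replicate 1 (0.836), lens higher without dark adapted replicate 3 (0.949), pigment epithelium higher without dark adapted replicate 3 (0.667) and light damaged replicate 3 (0.989), and circadian lower without dark adapted replicates 2 (0.724) and 3 (0.388) and light damaged replicate 1 (0.614). Adjusted p then lay between 0.592 and 0.881 for the bipolar list, 0.00113 and 0.115 for cell death, 0.142 and 0.772 for circadian, 0.00483 and 0.836 for glycolysis, 2.42e-08 and 0.74 for crystallin, 0.192 and 0.989 for pigment epithelium and 0.000186 and 0.949 for lens.

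The 45 named genes past the threshold kept it in 716 of 807 fits, lost it in 91 and never turned; 15 never lost it. Without dark adapted replicates 1, 2 and 3 they lost 4, 11 and 4 calls, and without light damaged replicates 1, 2 and 3 they lost 9, 12 and 14. They lost 27 with no block and without both replicate 3 arrays, 6 on reference-centred arrays (Sox2, Cxcl12, Ccl12, Atf5, Timp1 and Rdh10), 2 with mean probe sets (Cxcl12 and Tap1), 1 without probe sets of several transcripts (Mt1) and 1 with a variance trend (Nrl). The rod minus cone difference, with Gnb3 in the cone list throughout, kept its sign, between -0.22 and -0.08 with 1 array left out. Genes near the floor of RMA values, close to background, have compressed changes.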

Other observations

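The genes below, beyond Fgf2 and Hcls1, were chosen after their values were seen, from the largest changes past the threshold not yet named. Of the 316 genes that rose, 244 were in none of the main lists, and of the 49 that fell, 43. Outside the lists, the receptor tyrosine kinase genes Met and Axl rose, Met from 5.85 ± 0.33 to 8.15 ± 0.08 and Axl from 6.68 ± 0.49 to 8.88 ± 0.06 (mean ± SD, n = 3 per group). So did Aldh1l1, an enzyme used as an astrocyte marker (2.27 ± 0.16, SE), the urea transporter gene Slc14a1 (2.17), the serine protease gene Prss56 (2.42), the galectin gene Lgals1 (2.39) and the chitinase-like gene Chil1 (2.37). Interferon-inducible genes beyond the list included Ifitm3 (2.34), Gbp6 (2.26), Ifitm1 (2.13) and Parp12 (1.94). Nudt6, which lies on the strand opposite Fgf2 and overlaps it, rose by 2.05 ± 0.27 (SE), beside 1.72 ± 0.31 for Fgf2. The adjusted p of these genes other than Fgf2 in limma lay between 0.000757 and 0.00766.

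Among the falls outside the lists were genes known from photoreceptors, namely Reep6 (-1.23), the potassium channel subunit gene Kcnv2 (-1.01) and Pitpnm3 (-1.37), with adjusted p of 0.046, 0.0203 and 0.0137. The linker histone gene H1f2 fell by 1.41 from a high level of 11.10 ± 0.22 (SD, n = 3), the ectonucleotidase gene Nt5e fell by 1.23 and the water channel gene Aqp1 by 1.13. The gene Tnfaip3, an inhibitor of NF-kappaB signalling, fell by 1.25 (adjusted p = 0.0154), and Hcls1 and Sh2d1a, both known from blood cells, fell by 1.52 and 1.27. The iron handling gene that fell was Hfe, a regulator of iron uptake (-1.32, adjusted p = 0.00565).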
